A study of Mus musculus with 4 samples.

How the data were processed

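CTCF and RAD21 were mapped by ChIPmentation, a form of chromatin immunoprecipitation in which the Tn5 transposase adds sequencing adapters to chromatin while it is still on the antibody beads. The material was mouse gastruloids, aggregates of embryonic stem cells that form a body axis in culture, pooled and fixed 96 h after aggregation. There were 4 libraries and 1 library per group: CTCF in wild-type gastruloids, CTCF in a HoxB mutant that carries inserted CTCF binding sites (InsCBS5-10), CTCF in the same mutant after removal of sites 7 to 10 (DelCBS7-10), and RAD21 in InsCBS5-10. Groups were taken from the sample titles. In both mutants, per the labels, 1 copy of HoxB is deleted and the other lacks the interval between Hoxb9 and Hoxb13 (i9-13).

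The deposited values are peak lists in MACS2 narrowPeak form, made separately for each library. Per the submitters' processing notes, the tools were cutadapt 4.1 and MACS2 2.2.7.1 and the genome build was mm10. The peak names show that the authors aligned all libraries to an edited mm10 with 2 versions of chromosome 11, a version that carries the insertion and a version without HoxB. The aligner, the filter on mapping quality, the control library and the options of the peak caller are not given in the sources used here. Each peak has the authors' score, which is 10 times the −log10 q as a whole number. The deposited fold enrichment is a ratio of the signal at the summit to the local background of the same library. The deposited −log10 p and −log10 q were also computed within each library. The smallest −log10 q was 1.30 in each list, which corresponds to a q threshold of 0.05. These values are the authors', and were used only to describe, rank or filter peaks within a list. Numbers of reads are unknown from these peak lists, so depth could not be taken into account, and a peak missing from a list was not called there rather than shown to be absent from the chromatin. A further peak list without a sample of its own (1 list, RAD21 in wild type) was not analysed here.

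Summits that shared an interval were merged to 1 peak at the strongest summit, and peaks on chromosomes 1 to 19, X and Y were kept. The chromosome 11 version without HoxB was left out. Reads of sequence shared by both versions have no unique place, and how they were shared out is not given in the sources used here, so fold enrichment on chromosome 11 is not comparable with that on other chromosomes. HoxB itself has 2 copies in wild type and 1 copy in the mutants, so fold enrichment at HoxB can be lower in the mutants for that reason alone. No list of artifact-prone regions was applied.

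A peak was counted as found in another list where it overlapped a peak there by 1 bp or more. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Peaks were also split into 10 strength classes (deciles) by fold enrichment within their own list. With no replicates, no test between genotypes was made and no p-value is given. Sets of peaks missing from a list were instead compared with 10000 random sets of peaks from the same list with the same deciles. The percentage of random sets that missed as many peaks describes these lists only. Runs of consecutive missing peaks were counted along each chromosome among the peaks called in both other CTCF lists, and compared with 10000 shuffles of the missing peaks within deciles. A score for each run, chosen after the data were seen, adds −log10 of the share missing in the decile of each of its peaks, and the highest score anywhere in each shuffle was compared with it. On a simulated list of 34499 peaks, a planted share of 27.6% missing peaks came back as 27.6%, a planted run of 8 missing peaks was found, shuffles scored as high as this run in 53.4% of cases and as high as a run of 8 strong peaks in 0%, and 2 of 200 sets with nothing planted fell under 5%.

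Gene positions came from an annotation table of GRCm38, the assembly that mm10 names. The table has no strand, so the distance to a transcription start was replaced by the distance to the nearer of both ends of a protein-coding gene. Positions on chromosome 11 up to Hoxb13 are those of mm10, and positions beyond it are those of the edited sequence. The shift beyond the edit was estimated as 64.6 kb, the offset that put the most CTCF and RAD21 summits within 200 bp of gene ends. It placed 41 of 892 sites there, against at most 37 at offsets more than 1 kb away. The same scan gave an offset within 300 bp of 0 for 17 of 18 control chromosomes. The estimate was used to name neighbouring Hoxb genes and to set the limits of the HoxB region, of the interval from Hoxb13 to Hoxb9 and of the cluster. Peak counts and random sets for these parts therefore rest on it. No other gene beyond Hoxb13 on chromosome 11 was measured. A difference of 110.1 kb in position between both versions of chromosome 11, added to this shift, gives 174.7 kb, against 173.9 kb from the start of Hoxb13 to the end of Hoxb1 in the annotation. Numbers CBS5 to CBS10 were not assigned to peaks. The planned search for the CTCF consensus sequence was not run, since no genome sequence was used here.

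Most of the peaks and genes named were chosen by rules fixed before the data were examined. They were every peak between Hoxb13 and Hoxb9 and the strongest 4 per library in the rest of the HoxB region (100 kb to each side); for each pair of lists, the 8 strongest peaks missing from the other list within 5 kb of a gene end; the 5 strongest peaks of each list; at most 5 members per gene list whose call differed between CTCF libraries; and at most 5 runs of 3 or more missing peaks per list. A peak that these rules select is not reported here. There were 13 gene lists: posterior growth zone, neural, somite, endoderm, heart and vessel, pluripotency, extra-embryonic, CTCF and cohesin, imprinted domains, HoxA, HoxC, HoxD and clustered protocadherins. Other peaks named within HoxB, the windows around the other Hox clusters, the H19 region, the limit of 4 Mb on chromosome Y, the width of 800 bp and a list of developmental transcription factor families were chosen after the data were seen. Gene-list members named although their call did not differ, such as Tbx6, Cdx2, Cdx4, Foxa2, Meg3 and Hoxc10, were chosen outside these rules. Alternatives tried were a stricter threshold (−log10 q of 5 or more), other definitions of overlap, equal numbers of peaks per list and other distances to genes. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.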

Results

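Peaks of CTCF, the DNA-binding protein that stops loop extrusion at domain borders, were compared between 3 genotypes of mouse gastruloids at 96 h, and peaks of RAD21, a subunit of the cohesin ring, were compared with CTCF in InsCBS5-10. The wild-type CTCF list held 47931 peaks, InsCBS5-10 held 34499, DelCBS7-10 held 36589, and the RAD21 list held 19610. Median fold enrichment was 5.60, 5.56, 5.30 and 6.17 in the same order. The share of peaks with a −log10 q of 5 or more was 72.6%, 73.5%, 71.9% and 79.3%. There was 1 library per group, so differences between lists have no replicate check.

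The title of the series asks about insulation of Hoxb13, the last and most posterior gene of the HoxB cluster, by CTCF. The first comparison was therefore of the peaks between Hoxb13 and Hoxb9, where the CTCF binding sites lie. Wild type had 5 CTCF peaks there, InsCBS5-10 had 4, and DelCBS7-10 had 1. All libraries were aligned to the edited chromosome 11, where this interval is shorter than in mm10 by an estimated 64.6 kb, so wild-type peaks in the sequence left out cannot appear and 5 is not the full wild-type count. In InsCBS5-10 the peaks lay on the edited chromosome 11 at 96199499 to 96199703 (fold enrichment 4.43, −log10 q 7.0), 96199991 to 96200180 (5.01 and 9.21), 96200547 to 96200791 (5.21 and 9.98) and 96201619 to 96201812 (4.71 and 7.91). The first 3 of these had no peak in DelCBS7-10. The only DelCBS7-10 peak, at 96201498 to 96202052 (fold enrichment 4.19, −log10 q 3.58), overlapped the last. RAD21 was called in InsCBS5-10 at 96199955 to 96200179 (fold enrichment 5.75, −log10 q 8.79) and 96200572 to 96200753 (6.20 and 10.4), which are the middle 2 of the 4 CTCF peaks.

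All 4 InsCBS5-10 peaks of this interval coincided with wild-type peaks. Reads of the same sites fall at the same positions of the edited sequence in each genotype, so the shared positions follow from the alignment. They are not positions in the wild-type locus. The wild-type peaks were at 96199505 to 96199711 (fold enrichment 2.68, −log10 q 5.18), 96199985 to 96200202 (5.70 and 32.0), 96200510 to 96200849 (7.61 and 54.2) and 96201521 to 96201832 (6.96 and 45.8). The fifth wild-type peak, at 96198946 to 96199099 (fold enrichment 2.46, −log10 q 3.85), had no counterpart in either mutant. Of random InsCBS5-10 peak sets with the same strengths, 0.66% missed 3 or more of 4 peaks in DelCBS7-10 (1.57% when drawn from chromosome 11). Strength here is the decile of fold enrichment, which is not comparable between chromosome 11 and other chromosomes. Most of chromosome 11 is also in both versions, while this interval is in 1, so the sets are matched only roughly. The 3 missing peaks spanned 1293 bp, the shortest span of the 38 runs of 3 or more consecutive peaks missing from DelCBS7-10, whose median span was 108 kb; this ranking was chosen after the data were seen. By a score of run length and peak strength, also chosen afterwards, 16 runs missing from DelCBS7-10 scored higher, and 99.98% of shuffles had a run as high somewhere. That comparison takes the highest run anywhere in the genome, whereas this interval was fixed beforehand. It therefore cannot decide whether the loss here exceeds what weak calling gives. A peak over deleted sequence cannot be called, so a missing peak does not separate lost sequence from lost binding.

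**Figure D1:**
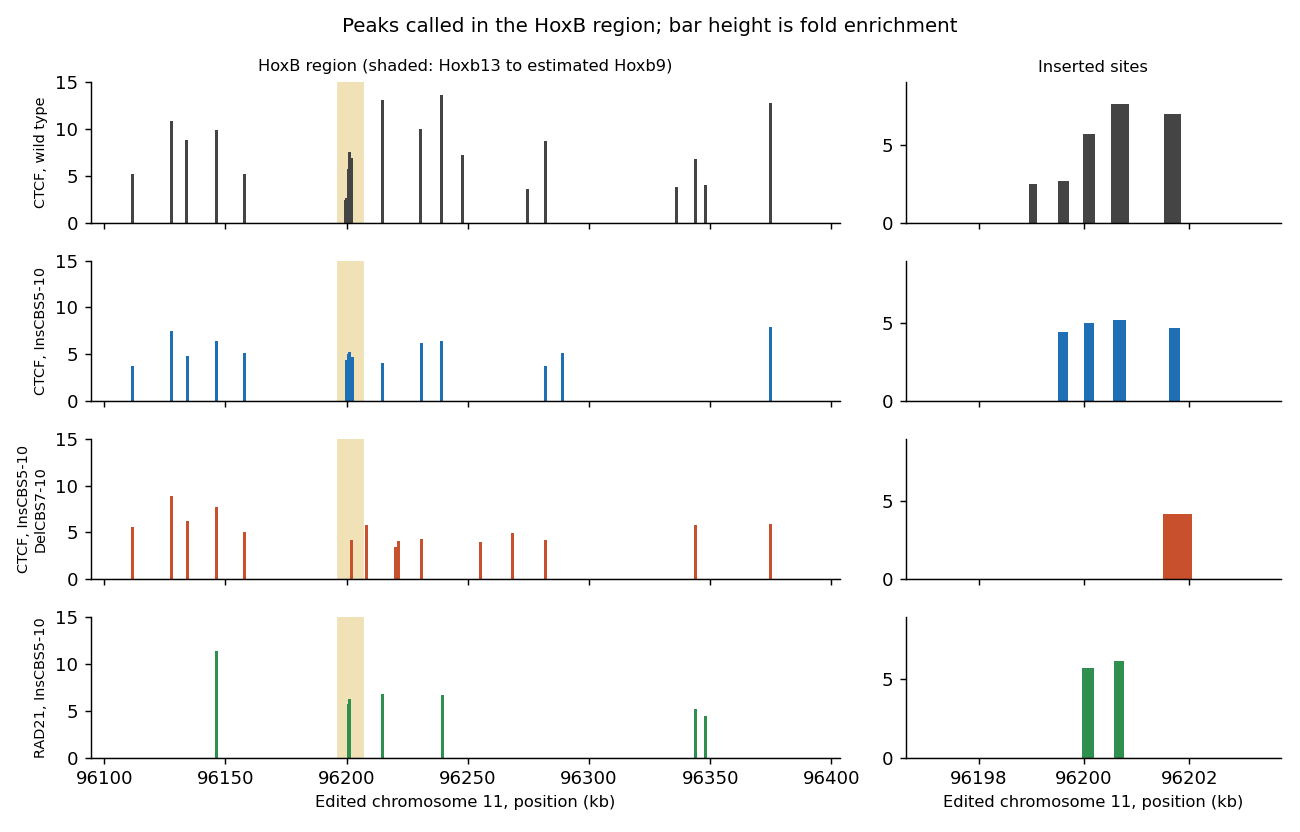
CTCF and RAD21 peaks in the HoxB region of the edited chromosome 11 (position in kb), with the height of each bar giving its fold enrichment, in each of the 4 libraries. The part with peaks of the shaded interval, from Hoxb13 to the estimated position of Hoxb9, is enlarged on the right and shows 5 CTCF peaks in wild type, 4 in InsCBS5-10 and 1 in DelCBS7-10, with 2 RAD21 peaks.

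The flank before Hoxb13 kept its CTCF peaks in each genotype, while the flank beyond Hoxb1 and the cluster itself did not. HoxB has 1 copy in the mutants, which bears on the calls within the cluster. All 5 sites before Hoxb13 were called in all 3 CTCF lists, and the site at 96145632 to 96146014 also carried RAD21 (fold enrichment 11.4, −log10 q 35.4). Beyond Hoxb1, at the other end of the cluster, 1 of 4 sites was called in all 3 CTCF lists. From Hoxb9 to Hoxb1, wild type had 6 CTCF peaks, InsCBS5-10 had 5 and DelCBS7-10 had 7, at 12 sites of which 2 were shared by all 3 lists. The shared sites were within Hoxb6, at 96230025 to 96230489 in wild type, and within Hoxb3, at 96281557 to 96281887.

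The strongest wild-type peaks outside the interval from Hoxb13 to Hoxb9 lay between Hoxb6 and Hoxb5 (96238556 to 96238976, fold enrichment 13.7, −log10 q 78.8), between Hoxb9 and Hoxb8 (96214227 to 96214672, 13.1 and 59.3), beyond Hoxb1 (96374222 to 96374618, 12.7 and 48.0) and before Hoxb13 (96127019 to 96127413, 10.8 and 38.0). The peaks between Hoxb6 and Hoxb5 and between Hoxb9 and Hoxb8 were also called in InsCBS5-10, at folds of 6.44 and 4.12, and carried RAD21 there, at 6.70 and 6.80. Neither was called in DelCBS7-10. In InsCBS5-10 the strongest were the sites beyond Hoxb1 (7.95), before Hoxb13 (7.47 at 96127064 and 6.41 at 96145593) and between Hoxb6 and Hoxb5 (6.44). In DelCBS7-10 they were sites before Hoxb13 (8.94 at 96127046, 7.68 at 96145718 and 6.22 at 96133547) and the site beyond Hoxb1 (5.86). RAD21 had its strongest 4 before Hoxb13 (11.4), between Hoxb9 and Hoxb8 (6.80), between Hoxb6 and Hoxb5 (6.70) and beyond Hoxb1 (5.22 at 96343303).

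Within the cluster, 5 sites were called in DelCBS7-10 alone, and these were singled out after their values were seen. They lay within Hoxb9 (96207494 to 96207979, fold enrichment 5.80, −log10 q 7.95), within Hoxb8 (96219718 to 96219914, 3.46 and 2.68, and 96220592 to 96220803, 4.05 and 4.09), over Hoxb4 and Hoxb3 (96254798 to 96255643, 3.98 and 3.27) and within Hoxb3 (96267593 to 96268135, 4.93 and 6.46). Only 2 of these 5 had a −log10 q of 5 or more, and with that limit DelCBS7-10 had 9 HoxB peaks in place of 15. Over the whole HoxB region, 6 of the 15 InsCBS5-10 peaks had no counterpart in DelCBS7-10, as many as in 0.73% of random sets (2.15% when drawn from chromosome 11). Without the interval from Hoxb13 to Hoxb9, 3 of 11 had none, as many as in 21.9% of random sets (28.9% from chromosome 11). Of the 15 wild-type peaks outside that interval, 6 had none in DelCBS7-10 (1.12% of random sets, and 5.23% from chromosome 11) and 5 had none in InsCBS5-10 (10.5% and 26.45%), and the lower copy number of HoxB in both mutants bears on these counts. All these random sets too are matched on strength only roughly.

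Across the genome, weak CTCF peaks were shared by the genotypes less often than strong ones. Of wild-type peaks, 63.2% (95% interval 62.8 to 63.7) were found in InsCBS5-10 and 65.8% (65.4 to 66.2) in DelCBS7-10. In the other direction, 87.7% (87.4 to 88.1) of InsCBS5-10 peaks and 86.0% (85.6 to 86.3) of DelCBS7-10 peaks were found in wild type. From the weakest to the strongest decile of wild-type peaks, the share found in InsCBS5-10 rose from 11.1% to 98.8%. Of the weakest decile in the mutants, 42.5% of InsCBS5-10 peaks and 46.2% of DelCBS7-10 peaks were found in wild type. Wild-type peaks found in neither mutant numbered 13686 (28.6%), with a median fold enrichment of 3.22, and those found in both numbered 27596, with a median of 8.00.

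**Figure D2:**
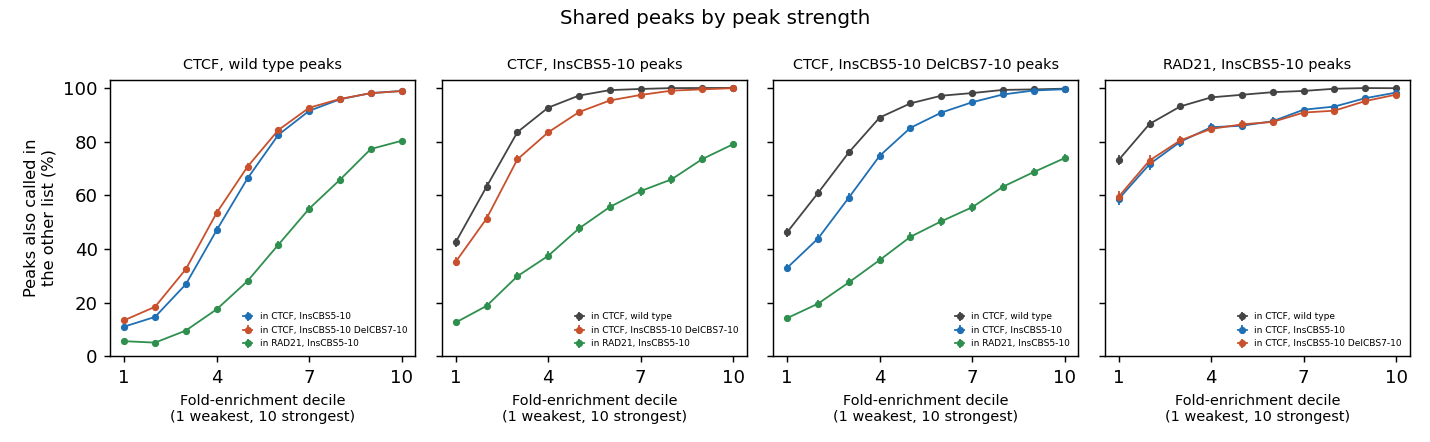
Share of the peaks of each list (panels) that were also called in each other list (lines, percent), by decile of fold enrichment within the list from weakest to strongest, with bars for exact 95% intervals. The share of wild-type peaks found in InsCBS5-10 runs from 11.1% in the weakest decile to 98.8% in the strongest.

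Wild type was compared with InsCBS5-10, which has the rearranged HoxB locus. With 1 library each, differences cannot be assigned to that locus rather than to the library or the stem cell clone. The strongest wild-type peaks near genes that were missing from InsCBS5-10 lay by Kpna1, an importin (chromosome 16, 35981682 to 35981816, fold enrichment 22.4), Capn8, a calpain protease (chromosome 1, 182629726 to 182629907, 18.0), and Nyx (chromosome X, 13461488 to 13461950, 17.3). Others were by Utp6, a ribosome assembly factor (17.0), Kctd6 (16.6), Carm1, an arginine methyltransferase (16.6), and Med13, a Mediator subunit (15.6). Of the peaks named, those by Carm1 and Med13 were called in DelCBS7-10, and the site by Nyx carried RAD21 in InsCBS5-10. Among the strongest 3 deciles of wild-type peaks, 33.9% (28.9 to 39.2) of the 339 missing from InsCBS5-10 lay within 1 kb of a gene end, against 12.4% (11.8 to 12.9) of those found. Over all wild-type peaks the shares were 8.99% (8.57 to 9.43) of those missing and 9.36% (9.03 to 9.70) of those found. For DelCBS7-10 they were 19.1% (15.0 to 23.8) and 12.7% (12.2 to 13.3) in the strongest 3 deciles, and 7.79% (7.38 to 8.21) and 9.98% (9.65 to 10.3) over all.

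Among InsCBS5-10 peaks missing from wild type, the strongest near genes lay by Il31ra, a cytokine receptor (chromosome 13, 112578187 to 112578353, fold enrichment 12.9), Spag6, a sperm flagellum protein (chromosome 2, 18693973 to 18694479, 8.83), and Dlx5, a homeobox transcription factor (chromosome 6, 6874239 to 6874761, 7.80). Peaks by Pkd1 (6.85), Orai2 (6.52), Dcaf15 (6.43), Tfap2d (6.25) and Uimc1 (6.21) followed. All but the peak by Il31ra were also called in DelCBS7-10, and those by Il31ra, Spag6 and Dlx5 carried RAD21.

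Wild type and DelCBS7-10, where sites 7 to 10 are removed as well, were compared in the same way and with the same limit. Among the strongest wild-type peaks near genes missing from DelCBS7-10, those by Kpna1, Capn8, Nyx, Utp6 and Kctd6 were also missing from InsCBS5-10. Further such peaks were by Pds5b, a regulator of cohesin (chromosome 5, 150673474 to 150673920, fold enrichment 17.0), and Nt5m (15.2), both called in InsCBS5-10 and with RAD21 there. Among DelCBS7-10 peaks missing from wild type, the strongest near genes were by Dlx5 (chromosome 6, 6874144 to 6874778, 14.3), Spag6 (14.2), Prdm6, a zinc-finger regulator (chromosome 18, 53463670 to 53464654, 13.8), and Cdkn2c, an inhibitor of cyclin-dependent kinases (10.5). They were followed by Sgpl1 (9.87), Nrn1 (9.41), Tfap2d (9.15) and Foxf1, a forkhead factor of lateral mesoderm (8.97). InsCBS5-10 had 6 of these 8, lacking those by Cdkn2c and Nrn1.

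The comparison of both mutants addresses the removal of sites 7 to 10. Of InsCBS5-10 peaks, 82.5% (82.1 to 82.9) were found in DelCBS7-10, and 77.7% (77.3 to 78.1) in the other direction. After the peak by Il31ra, the strongest InsCBS5-10 peaks near genes missing from DelCBS7-10 were by Dcaf12l1 (chromosome X, 44790257 to 44790446, fold enrichment 11), Isl1, a LIM-homeobox factor of heart and motor neurons (chromosome 13, 116311981 to 116312477, 7.93), Krcc1 (7.76), Zcchc2 (7.72), Grin2b, an NMDA receptor subunit (7.55), Tox3 (7.52) and E130309D02Rik (7.39). Wild type had 7 of these 8. DelCBS7-10 peaks missing from InsCBS5-10 were strongest by Cdkn2c (10.5), Vmn2r102, a vomeronasal receptor (9.42), Nrn1 (9.41), Timm8a1 (9.07), Gulp1 (8.87), Lhx5, a LIM-homeobox factor of the forebrain (8.38), Gm40847 (8.32) and Asgr1 (8.05), and wild type had 5 of these 8.

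A removed stretch of DNA takes out neighbouring peaks together, so runs of consecutive missing peaks were compared. Among 30266 peaks called in wild type and InsCBS5-10, 2736 (9.04%) were missing from DelCBS7-10, with 38 runs of 3 or more. The longest was of 6 peaks on chromosome Y (140586 to 263632), and 10.7% of shuffles had a run as long. Runs of 4 lay on chromosome 19 (32594016 to 32715565), chromosome 13 (61525660 to 62049355), chromosome 12 (115171546 to 115209377) and chromosome 1 (85162157 to 85181359). Missing from InsCBS5-10 were 3940 of 31449 peaks (12.5%), with 69 runs, and 35.9% of shuffles reached the longest run of 6. The longest lay on chromosome 17 (27202085 to 27514436), chromosome 12 (87900284 to 88370638), chromosome 1 (13227222 to 13500817), chromosome 7 (47244673 to 47781716) and chromosome 4 (146513389 to 146658079).

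Wild type lacked 932 (3.27%) of 28462 peaks called in both mutants, in 2 runs of 3. Shuffles had a run of 3 or more in 79.0% of cases. With a −log10 q of 5 or more in the lists that hold the peak, the longest run missing from wild type was of 2, so neither run of 3 remained, and those missing from InsCBS5-10 and DelCBS7-10 were of 4 and 6. The runs were on chromosome 13 (40709645 to 40731499) and on chromosome 7 (142580211 to 142582107). The latter lies just outside H19, at the imprinting control region where CTCF binds the unmethylated maternal copy. InsCBS5-10 had CTCF peaks there at 142580211 to 142580429 (fold enrichment 3.88), 142580614 to 142580826 (2.89) and 142581661 to 142582107 (4.37). DelCBS7-10 had them at 142580229 to 142580483 (4.31), 142580679 to 142580999 (4.26) and 142581717 to 142581991 (3.86). RAD21 was called at 142580136 to 142580907 (5.95). The neighbouring sites starting at 142532809, 142537909, 142552464 and 142610520 in wild type were called in all 3 CTCF lists, at folds of 10.2, 11, 4.58 and 6.18 in wild type, 4.79, 9.21, 4.85 and 5.22 in InsCBS5-10, and 6.89, 8.49, 4.70 and 4.90 in DelCBS7-10.

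**Figure D3:**
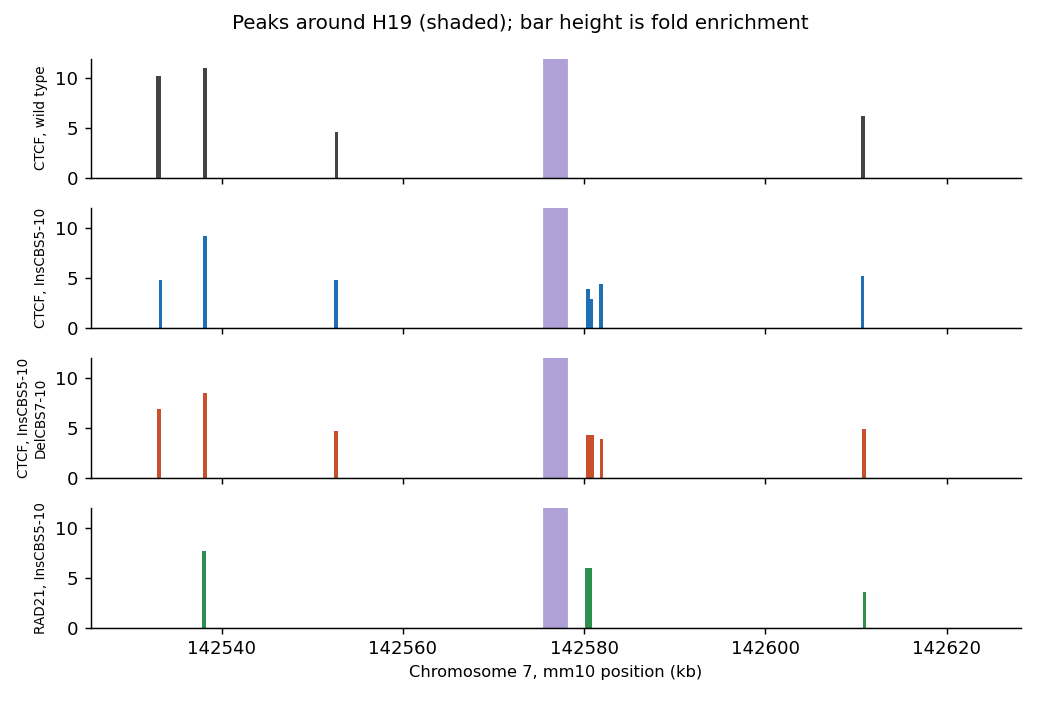
CTCF and RAD21 peaks within 50 kb of H19 (shaded) on chromosome 7, position in kb, with bar height giving fold enrichment in each of the 4 libraries. The 3 CTCF peaks just beyond H19, at folds of 2.89 to 4.37 in the mutants, have no counterpart in wild type.

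Cohesin sat mostly at the strong CTCF sites of InsCBS5-10. Of 34499 CTCF peaks, 48.2% (47.6 to 48.7) overlapped a RAD21 peak, from 12.6% of the weakest decile to 79.0% (77.6 to 80.3) of the strongest. The share was 56.7% for CTCF peaks called in all 3 genotypes and 2.18% for those called in InsCBS5-10 alone. It was 40.1% (38.3 to 41.8) within 1 kb of a gene end and 49.2% (48.6 to 49.7) elsewhere. In the other direction, 84.8% (84.3 to 85.3) of RAD21 peaks overlapped a CTCF peak of the same genotype, and summits of overlapping peaks lay a median of 22 bp apart (quartiles 10 and 41 bp). Only 889 RAD21 peaks (4.53%) were in none of the 3 CTCF lists.

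The strongest CTCF peaks near genes without RAD21 were by Nipsnap2 (chromosome 5, 129724718 to 129725146, fold enrichment 21.2), Nemf, a ribosome quality control factor (19.5), and Med4, a Mediator subunit (19.5). Peaks by Dus3l (17.3), Fcgr1 (17.2), Clcn4 (15.7), Vps13d (15.3) and Gdf15 (14.3) followed, and all 8 were called in all 3 CTCF lists. The strongest RAD21 peak near a gene without CTCF in InsCBS5-10 was within the HoxD cluster, by Hoxd10 (chromosome 2, 74691634 to 74691999, 13.4). Others were by Fgf18, a growth factor (12.9), Cfap126 (11.7), Pde1c (11.5), Asgr1 (11.3), Ap1s2 (10.5), Ppfia2 (10.4) and Nkx2-2, a homeobox factor of the ventral neural tube (10.3). All 8 sites had a CTCF peak in wild type, and all but that by Hoxd10 had one in DelCBS7-10.

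Genes of the developing body axis and of other fixed lists were next compared by their CTCF peaks within 5 kb of an end. Of 182 measured members of 13 lists, 140 had one in wild type, 134 in InsCBS5-10 and 134 in DelCBS7-10, and 102 had a RAD21 peak. Clustered protocadherins made up 57 of the 182 and 54 of the 140. Cdx2 was counted in both the posterior growth zone and the extra-embryonic list. The share over all protein-coding genes is not given here, so these counts show no trait particular to a list. All 3 CTCF lists had a peak near 126 members, none had one near 34, and the call differed for 22. A call counts any peak within 5 kb, and 8 of the 126 had no site that all 3 lists shared: Pax3, Tbx18, Isl1, Hoxc4, Hoxc5, Hoxc6, Hoxc8 and Hoxc9. The shorter distance of 1 kb gave 82, 75, 89 and 47 members in the same order, so the counts below depend on the distance, and those within 1 kb are given after them in the order wild type, InsCBS5-10, DelCBS7-10 and RAD21.

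In the posterior growth zone, the tail-end tissue that feeds axis elongation, 18 of 20 genes had a CTCF peak in wild type, 16 in each mutant, and 13 had RAD21 (within 1 kb 4, 4, 5 and 0). Tbx6, which drives presomitic mesoderm, had folds of 16.8 in wild type, 10.9 in InsCBS5-10 and 10.3 in DelCBS7-10, and Cdx2, a caudal regulator of posterior Hox genes, had 13.0, 7.36 and 6.08. Folds here and below are not on a common scale between lists. The strongest decile began at 11.4 in wild type, 8.86 in InsCBS5-10 and 8.26 in DelCBS7-10. A lower fold in a mutant therefore does not show less CTCF at a gene. The call differed for 4 members. T (Brachyury, 3.32) and Msgn1 (3.68) had a peak in wild type alone, Lin28a had peaks in wild type (5.38) and InsCBS5-10 (3.33), and Evx1 had one in DelCBS7-10 alone (3.53). The peaks by T and Msgn1 were weak, in wild-type deciles of which 14.7% and 26.9% were found in InsCBS5-10. At a −log10 q of 5 or more, 16, 15 and 15 members had a peak in wild type, InsCBS5-10 and DelCBS7-10. Cdx4 had none in any CTCF list.

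Of 8 neural genes, 6 had a CTCF peak in wild type, 5 in InsCBS5-10, 6 in DelCBS7-10 and 5 had RAD21 (within 1 kb 2, 2, 5 and 2). The call for Nkx6-1, a ventral neural tube factor, differed only through the limit of 5 kb, since its wild-type site (8.33) was called in all 3 lists, and it had RAD21 (9.74). The strongest DelCBS7-10 peak within 5 kb of this gene was a different one (101658805 to 101659556, 4.01). Of 10 measured somite genes, 7, 6 and 7 had a CTCF peak and 4 had RAD21 (within 1 kb 4, 3, 4 and 1), with Meox2 called in wild type alone (4.96) and Uncx in DelCBS7-10 alone (4.52). Endoderm genes (6 of 8 in each genotype, 3 with RAD21; within 1 kb 2, 1, 1 and 0) and heart and vessel genes (3 of 8 in each, 2 with RAD21; within 1 kb 0, 0, 1 and 0) had no member whose call differed, though for Isl1 the DelCBS7-10 peak (116309850 to 116310495, 3.82) was not the one called in wild type and InsCBS5-10. Foxa2, an endoderm pioneer factor, had folds of 16.8, 11.2 and 6.05, and Gata4, a cardiac factor, had 10.1, 8.38 and 6.02.

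Pluripotency genes had a CTCF peak for 4 of 6 members in wild type and 2 in each mutant, with 2 for RAD21 (within 1 kb 1, 0, 0 and 0). At a −log10 q of 5 or more, wild type had 2 as well, so this difference rests on weak peaks. Nanog (3.43) and Esrrb (3.73) were called in wild type alone, and Pou5f1 (8.85, 6.66 and 5.12) and Klf4 (11.6, 7.05 and 8.00) in all. Extra-embryonic markers, included for other cell types that aggregates could hold, had peaks for 3, 4 and 3 of 6 members and 2 for RAD21 (1 at a −log10 q of 5 or more; within 1 kb 2, 3, 3 and 0), with Ttr called in InsCBS5-10 alone (4.00). Genes for CTCF and cohesin had peaks for 8, 6 and 5 of 12 members and 5 for RAD21 (within 1 kb 5, 4, 3 and 2). With a −log10 q of 5 or more, the CTCF counts were 7, 5 and 5. Pds5b had folds of 17.0 in wild type and 4.27 in InsCBS5-10 and no CTCF peak in DelCBS7-10, and Nipbl (2.84) and Mau2 (4.75), which load cohesin, were called in wild type alone.

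Imprinted genes had a CTCF peak for 9 of 18 members in wild type, 10 in InsCBS5-10 and 9 in DelCBS7-10, and 6 had RAD21 (within 1 kb 2, 1, 1 and 1). H19 was called in both mutants and not in wild type, Dlk1 in InsCBS5-10 alone (3.37) and Nnat in wild type alone (5.07). Meg3 (18.0, 11.4 and 10.8) and Plagl1 (12.2, 7.90 and 6.37) were called in all 3 genotypes. Clustered protocadherins, whose promoters are chosen through CTCF loops, had peaks for 54, 54 and 55 of 57 genes and 41 had RAD21 (within 1 kb 53, 49, 53 and 37). By the lower-coordinate end alone, CTCF was near 52, 49 and 52 and RAD21 near 27, and RAD21 was near 26 by either end at a −log10 q of 5 or more. Pcdha11 had peaks in wild type (3.14) and DelCBS7-10 (3.49), Pcdhb1 in InsCBS5-10 alone (3.09) and Pcdhb9 in DelCBS7-10 alone (5.16).

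In the other Hox clusters, neighbouring genes can share a peak and the counts depend on the distance. HoxA had 8, 8 and 7 of 11 genes with a peak in wild type, InsCBS5-10 and DelCBS7-10, HoxC had 7, 8 and 8 of 9, and HoxD had 7, 6 and 7 of 9. RAD21 was near 5, 7 and 7 genes of these clusters. Within 1 kb, the CTCF counts were 3, 3 and 4 for HoxA, 2, 3 and 5 for HoxC and 2, 2 and 4 for HoxD, and RAD21 was near 2, 2 and 0 genes. Hoxa13 had folds of 8.88 in wild type and 5.14 in InsCBS5-10, no CTCF peak in DelCBS7-10, and RAD21 at 12.1. Hoxc11 was called in the mutants alone (5.76 and 6.71), and Hoxd12 had no CTCF peak in InsCBS5-10 and different ones in wild type (74672947 to 74673372, 13.2) and DelCBS7-10 (74681478 to 74682563, 6.14). Hoxc10, with folds of 17.0, 12.6 and 8.87, was called in all 3.

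The strongest peaks of each list were mostly the same places. Of the 5 strongest peaks in each of the 4 lists, 15 of 20 were found in all 4. These 20 peaks had a −log10 q of 359 to 7023, against 158 for the strong CTCF peak by Nipsnap2 in InsCBS5-10. No list of artifact-prone regions was applied, so these places may not be binding sites, which was not tested. The leading peak of each list was on chromosome 6 at 103649051 to 103649291, with folds of 52.3 in wild type, 49.7 in InsCBS5-10, 48.0 in DelCBS7-10 and 45.2 for RAD21, and the next in both mutants and RAD21 was on chromosome 12 at 3109872 (45.7, 45.1 and 42.3). Other leading places were chromosome 9 at 24542005 and 35305219, chromosome 5 at 60042722 and, for RAD21, chromosome 12 at 97061432 (34.2). In wild type, chromosome 11 at 121917880 on the edited sequence (44.1) and chromosome 13 at 77438909 to 77439055 (50.6) were also among the first 5, and the latter was in no other list. Near gene ends, within 1 kb, lay 9.22% (8.96 to 9.49) of wild-type peaks, 8.90% (8.60 to 9.21) of InsCBS5-10 peaks, 9.78% (9.47 to 10.1) of DelCBS7-10 peaks and 7.25% (6.89 to 7.62) of RAD21 peaks.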

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

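No test was run on the values in this part, and no explanation of them was tested. The chromosome 11 version without HoxB, which the comparisons did not use, held 2346 peaks in wild-type CTCF, 1823 in InsCBS5-10 CTCF, 1913 in DelCBS7-10 CTCF and 898 in RAD21. The version that was used held 2308, 1793, 1890 and 871. The mitochondrial genome, also left out, held 6 peaks in wild-type CTCF, 3 in InsCBS5-10 CTCF, 2 in DelCBS7-10 CTCF and 3 in RAD21. There were no control samples, so these counts stand out only because they are above 0 in sequence left out of the comparisons.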

How the results depend on the processing

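Random sets drawn from chromosome 11 or matched on −log10 q, protocadherins by their lower-coordinate end and the wider Hox windows were chosen after the data were seen, and the other alternatives were planned. Of 199 alternatives, 97 left a value within its 95% interval (for random sets, the interval of their percentage) or a count within 1.5 times, and 102 moved it. All 30 shares of CTCF peaks found in another genotype moved, always in the order wild type in InsCBS5-10, wild type in DelCBS7-10, InsCBS5-10 in wild type, InsCBS5-10 in DelCBS7-10, DelCBS7-10 in wild type and DelCBS7-10 in InsCBS5-10. A −log10 q of 5 or more in both lists gave 70.3%, 71.3%, 96.3%, 87.1%, 94.1% and 83.9%, and in the first list alone 81.7%, 83.8%, 98.3%, 95.1%, 97.1% and 92.5%, since weak peaks leave the list. Reciprocal overlap by 0.5 gave 56.6%, 58.5%, 78.7%, 72.9%, 76.7% and 68.7%, and summits within 100 bp gave 59.8%, 61.7%, 83.1%, 76.8%, 80.8% and 72.4%, by being stricter. The strongest 34499 peaks of each list gave 82.1%, 82.9%, 82.1%, 81.3%, 82.8% and 81.1%, where equal list lengths alone make both directions of a pair nearly equal.

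Shares of CTCF with RAD21 and of RAD21 with CTCF were 51.2% and 83.5% at a −log10 q of 5 or more in both lists, 45.6% and 80.2% for summits within 100 bp, 38.2% and 67.3% for reciprocal overlap, and 65.4% and 65.6% for the strongest 19610 peaks of both. For the first of these the cause was not tested. DelCBS7-10 kept 9 HoxB peaks at a −log10 q of 5 or more, while the other HoxB counts stayed within 1.5 times. Within 500 bp of a gene end lay 5.96%, 5.50%, 6.08% and 4.31% of wild-type, InsCBS5-10, DelCBS7-10 and RAD21 peaks, and a −log10 q of 5 or more gave 10.7% for wild type and 9.51% for InsCBS5-10, for which the cause was not tested. Gene lists within 1 kb of a gene end held 82, 75, 89 and 47 members with a peak. Of 104 alternatives for single gene lists, 46 moved, all to lower counts.

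Between Hoxb13 and Hoxb9, DelCBS7-10 lacked 3 of the 4 InsCBS5-10 peaks by overlap and by summits, and all 4 by reciprocal overlap or at a −log10 q of 5 or more. Random sets drawn from chromosome 11 missed as many in 1.57% of cases and sets matched on −log10 q in 0.37%, which both moved from 0.66%. For lost Hox peaks, 50 kb to each side moved 0.23% to 1.47%. Sets drawn from chromosome 11 raised all 4 percentages for missing HoxB peaks. By the lower-coordinate end, 52, 49 and 52 protocadherins had a CTCF peak and 27 had RAD21. Neither alternative for the CTCF consensus search was run, since no genome sequence was used here. No paired analysis was possible because each group has 1 library.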

Other observations

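The tests in this part were chosen after the results were seen, except the share of Hox peaks near gene ends, whose reading was set beforehand.

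HoxA, HoxC and HoxD, with 5 kb to each side, held 17 CTCF peaks in wild type, 17 in InsCBS5-10 and 26 in DelCBS7-10. DelCBS7-10 lacked 5 of the wild-type peaks, near Hoxa13 (chromosome 6, 52256924 to 52257370), Hoxc8 (chromosome 15, 102987454 to 102987800), Hoxc5 (chromosome 15, 103013559 to 103013930), Hoxd13 (chromosome 2, 74672947 to 74673372) and Hoxd10 (chromosome 2, 74691585 to 74691902). All 5 sites carried RAD21 in InsCBS5-10. Those near Hoxd13 and Hoxd10 had no CTCF peak in InsCBS5-10 either, although RAD21 was called there (7.85 and 13.4). In turn, 14 of the 26 DelCBS7-10 peaks were missing from wild type. Of 10000 random sets, 0% missed as many, both with 5 kb and with 50 kb to each side, but the windows were chosen after the missing peaks had been seen. Of the 14, 12 were in no other CTCF list, had a median width of 443.5 bp and overlapped 0 RAD21 peaks. RAD21 was analysed in InsCBS5-10 only, where these 12 had no CTCF peak, so the 0 shows nothing particular about them. Even of CTCF peaks called in InsCBS5-10 alone, 2.18% overlapped RAD21. The widest of the 12 lay by Hoxc9 (chromosome 15, 102976009 to 102977486, fold enrichment 6.56) and over Hoxd13 (chromosome 2, 74668285 to 74669404, 7.19).

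Across the genome, Hox clusters included, 64 DelCBS7-10 peaks of 800 bp or more were missing from wild type. Both this width and a list of developmental transcription factor families were chosen after these peaks had been seen, so the shares below describe them and test nothing. The nearest gene belonged to such a family for 39 of 63 with a gene (61.9%, 95% interval 48.8 to 73.9) and to none for 24. The share was 1.28% (0.681 to 2.17) of the 1019 wide peaks found in wild type. Of the 64, 27 were also called in InsCBS5-10, among them those by Prdm6, Tfap2d, Foxf1 and Pax7. Examples were Prdm6 (13.8), Vax2 (9.46), Tfap2d (9.15), Foxf1 (8.97), Lhx5 (8.38), Pax7 (7.62) and Nkx2-1 (6.29). RAD21 in InsCBS5-10 overlapped 5 of the 64, against 665 of the 1024 found in wild type. Narrower DelCBS7-10 peaks were split the same way, with 149 of the 5076 missing from wild type and 15761 of the 30425 found there. Little RAD21 is therefore not particular to the wide peaks. In InsCBS5-10, 6 peaks of 800 bp or more were missing from wild type.

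Wild-type Hox peaks too weak to be called again in DelCBS7-10 stay open: 0.23% of random sets of the same strengths missed 5 or more of 17 (1.47% with 50 kb to each side), but on windows chosen after the missing peaks had been seen. Wider peaks throughout the DelCBS7-10 list are argued against only for its contrast with InsCBS5-10, as 2.97% of peaks reached 800 bp in DelCBS7-10 (2.80 to 3.15) and the same 2.97% in InsCBS5-10 (2.79 to 3.15), while wider peaks in both mutant lists than in wild type stay open, since wild type had 0.778% (0.701 to 0.861). For a loss shared by both mutants, under 5% of random sets were expected to miss as many as InsCBS5-10. It missed 3 of 17, as many as 17.1% of random sets, which went against a shared loss. So few peaks cannot exclude a shared loss, which stays open. More signal from open promoters may also account for the gained peaks: 50.0% (23.0 to 77.0) of the 14 missing from wild type and 41.7% (15.2 to 72.3) of the 12 found there lay within 1 kb of a gene end, and the overlap set beforehand as evidence against it was a poor choice, since so few peaks give intervals this wide. Among the strongest 3 deciles of DelCBS7-10 peaks genome-wide, the share was 26.7% (16.1 to 39.7) of the 60 missing from wild type. It was 10.5% (9.89 to 11.1) of those found. Over all DelCBS7-10 peaks the order was the other way, 8.72% (7.96 to 9.53) and 9.95% (9.62 to 10.3), so these shares do not decide it. A change in genotype or in the mix of cells stays open and untested with 1 library per genotype.

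The H19 control region, with 3 CTCF peaks in each mutant and none in wild type, is a place where the parental origin of DNA sets CTCF binding. Peaks too weak to be called again stay open, since this run was picked from the whole genome and 100% of shuffles had a run somewhere with as high a score. Random sets of the same strengths missed 3 of 3 in wild type in 1.57% of cases for InsCBS5-10 and 0.67% for DelCBS7-10. The region was chosen after its peaks had been seen, so these low percentages exclude nothing. Another candidate explanation is a different methylation state of this region in the wild-type stem cell line, which was not tested, as no methylation data were analysed here. The genotypes themselves also stay open and untested.

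On chromosome Y below 4 Mb, wild type had 17 CTCF peaks, InsCBS5-10 had 6, DelCBS7-10 had 0 and RAD21 had 7. The run of 6 missing from DelCBS7-10 was picked as the longest, and 10.7% of shuffles had a run as long, but with peak strength counted 0% of 10000 shuffles had a run anywhere with as high a score, which argues against weakness as the reason. Loss of the whole chromosome Y from the DelCBS7-10 cells may be the cause, and it stays open. Beyond 4 Mb, DelCBS7-10 kept 35 peaks, against 38 in InsCBS5-10 and 78 in wild type. Of the 35, 33 were found in InsCBS5-10 and 31 in wild type. However, that part of the chromosome is repetitive and the reads there may come from other sequence. A shorter deletion and a difference between stem cell clones were not tested.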
